A study of Mus musculus with 4 samples.

How the data were processed

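Peripheral blood leukocytes of C57BL/6J mice aged 10 weeks were profiled by droplet single-cell RNA sequencing in a model of acute lymphoblastic leukaemia (ALL) treated with dasatinib, a tyrosine kinase inhibitor. Per the labels' protocols, blood was drawn 1 week after the start of dasatinib, when every mouse was in remission. The cells were cryopreserved, and the mice were treated for 4 more weeks and classed at day 100 as Cured (6 mice) or Relapsed (6 mice). Thawed live-sorted cells of 3 mice were pooled per library, giving 2 Cured and 2 Relapsed libraries, prepared with the 10x Genomics 5′ chemistry and sequenced on a NovaSeq instrument. The pool is the replicate throughout, because no cell can be traced to a mouse in the files used here.

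The deposited values are raw UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and cell barcode. Per the file headers and the submitters' processing notes, the authors made them with Cell Ranger 3.1.0 against mm10. The annotation release was not given in the sources used here. The count tables list 32287 features, among them the added sequences GFP_1 and BCR_ABL_1. Coordinates come from GENCODE release M21 on GRCm38, the assembly that mm10 names. Of the listed gene identifiers 32158 were found there and 129 were not. Counts over genes that overlap on the same strand or have near-identical copies are uncertain, since the counting rule for shared reads was not given in the sources used here.

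The 4 libraries held 16157 barcodes and 37141352 UMIs, each barcode with at least 500 UMIs. Barcodes with fewer than 200 genes (356), with more than 10% mitochondrial UMIs (362) or called doublets by Scrublet (7) were left out, which left 15432 cells. In Relapsed replicate 1, 279 barcodes had fewer than 200 genes, and haemoglobin UMIs dominated 277 of them. Cells were normalised, log-transformed and clustered with scanpy 1.11.5 on Python 3.11.15 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0 with leidenalg 0.10.2, seed 1). Clusters were named from the fixed markers, with at least 3 detected in 10% of cells. A cluster of 460 cells with a median of 602 UMIs, under the depth limit for naming, stayed unnamed, as did 24 cells led by haemoglobin genes. A B-lineage cluster led by Cdkn2a and single immunoglobulin segments was kept apart from B cells, where at least 25% of the cells carried Cdkn2a UMIs. The 7 Scrublet calls (0.0433% of barcodes) were too few to stand for all doublets. Cells carrying at least 3 markers each of more than 1 lineage (394 cells) were therefore left out of the classes as mixed. That rule, the depth limit for naming, the cluster kept apart, the list that names B cells, the T cell state rules and the CD4 or CD8 gate were set over several rounds after the clusters had been seen, with the cells per library in view and before any gene or share test was run.

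T cell clusters did not part CD4 from CD8 cells, so T cells were gated on UMIs of Cd4 or Cd40lg against Cd8a or Cd8b1. Among 1399 T cells, those with UMIs of neither or of both were left out of these classes. No regulatory T cell cluster was found. The state called both-marker carried markers of naive and of antigen-experienced cells.

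UMIs were summed per library and class where every library held at least 20 cells of the class. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 (TMM factors, filterByExpr, robust fit) on R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene or a share is from edgeR unless DESeq2 1.42.0 is named. A positive log2 fold change is higher in Cured. CPM values scale each count to the class sum of the library (cpm of edgeR), were computed here, and are given as mean ± SD over n = 2 libraries per group. Shares of cells were tested with edgeR on cell counts. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.333. Gene lists (31 fixed in advance) with at least 5 tested members were tested with camera of limma 3.58.1 at the preset correlation of 0.01, and also with an estimated correlation and with fry. The difference between the CD4 and CD8 effects was tested as an interaction with the library as a block.

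The tests, the gene lists, the marker genes and the rule for named genes were fixed before the data were examined, but not the rules that applied the markers to cells and clusters. That rule took, per class, up to 12 genes in each direction past the test whose libraries did not overlap between groups and whose mean CPM was at least 20, filled up to 6 by smallest p. It also took 24 genes of T cell function in CD4 and CD8 T cells and the 3 members with the smallest p of each list described. Antigen receptor segments, sex-linked, mitochondrial, ribosomal and predicted genes were set apart. Results of a few genes chosen in advance are not reported here. Genes named outside the rule are said to be so.

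The tests were tested on simulated counts with the real means and library sizes. Genes were drawn independently, with dispersions fitted by the same model and no shift shared by a library. The false calls below hold for such counts only. In CD8 T cells the gene test found 8.96% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 92.4% of those changed 4-fold, and 2 of its 98 calls were false. In CD4 T cells it found 13.4%, 28.4% and 83.3%, in B cells 14.9%, 55.2% and 90.9%, and in monocytes 8.96%, 35.8% and 83.3%. False calls were 7 of 114 in B cells (6.14%), 6 of 83 in NK cells (7.23%) and 7 of 92 in neutrophils (7.61%), above the 5% aimed at. Exact 95% binomial intervals and the limit of 3 counts for a count of 0 cover counting error only. Alternatives covered the normalisation, the count filter, DESeq2, the robust fit, the replicate number as a block, gene groups left out, cells thinned to 1000 UMIs, doublets, the mitochondrial limit, the resolution, marker gates and each library left out. A few more were added after the data had been seen.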

Results

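The study asked which features of blood leukocytes, early in dasatinib treatment, set apart mice that later stayed in remission from mice that later relapsed, with an interest in T cell immunity. The 2 Cured libraries held 3859 barcodes with 9257402 UMIs (replicate 1) and 4284 barcodes with 10840397 UMIs (replicate 2). The 2 Relapsed libraries held 3631 barcodes with 7184045 UMIs and 4383 barcodes with 9859508 UMIs. After filtering, 3776, 4135, 3252 and 4269 cells remained, in the same order. Median UMIs per cell were higher in both Cured libraries than in both Relapsed libraries in T cells (3393 and 3308 against 2982 and 3142.5), in B cells (2247.5 and 2363 against 1851 and 2034) and in NK cells (2076 and 1971.5 against 1556 and 1789). This depth gap runs alongside every gene comparison in those classes.

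Blood composition was compared first. B cells made up 70.7% ± 0.647 of kept cells in Cured and 68.2% ± 8.07 in Relapsed libraries (SD, n = 2 each). T cells made up 10.5% ± 1.60 against 7.68% ± 0.923, a log2 ratio of 0.45 (SE 0.24), and NK cells 4.65% ± 0.0591 against 5.74% ± 0.271. Neutrophils made up 5.73% ± 0.994 against 7.99% ± 5.44, monocytes 1.71% ± 1.11 against 2.62% ± 0.270, and dendritic cells 0.187% ± 0.0774 against 0.297% ± 0.320. Neutrophils were uneven between the Relapsed libraries, with 385 of 3252 cells in replicate 1 and 177 of 4269 in replicate 2. Without Relapsed replicate 1 the log2 ratio changed sign for neutrophils (-0.48 to 0.47) and B cells (0.05 to -0.06). The edgeR test called 0 of 9 classes (adjusted p = 0.460 for T cells, 0.460 for NK cells, 0.523 for monocytes, 0.625 for neutrophils and 0.820 for B cells), with 0 of them at an unadjusted p under 0.05. The exact permutation test could not go below 0.333.

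**Figure D1:**
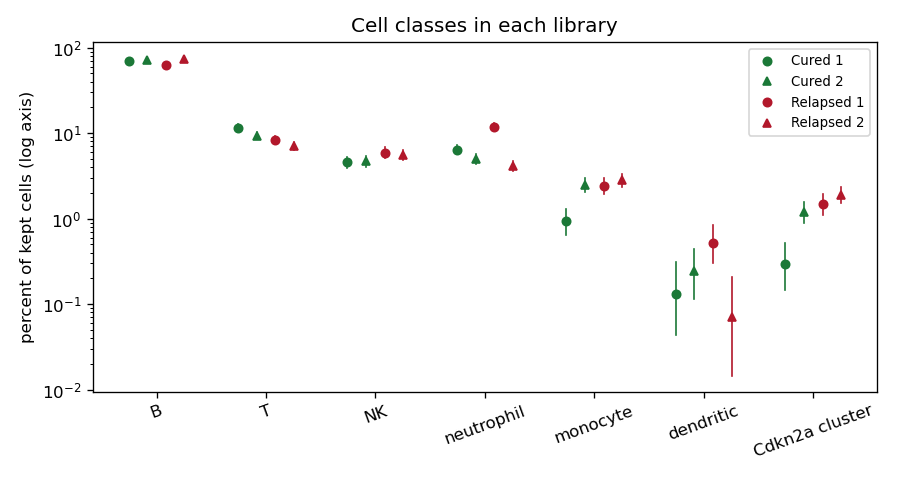
Share of kept cells in each cell class (percent, log axis) for the 4 libraries, with Cured in green, Relapsed in red, circles for replicate 1, triangles for replicate 2 and bars for exact 95% intervals. T cells lie at 11.7% and 9.38% in the Cured libraries and at 8.33% and 7.03% in the Relapsed libraries.

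Within T cells, naive-like CD4 cells made up 9.70% ± 0.862 of T cells in Cured and 6.30% ± 0.0426 in Relapsed libraries, a log2 ratio of 0.62 (SE 0.12, n = 2 each). Antigen-experienced-like CD4 cells made up 3.21% ± 1.65 against 1.61% ± 0.858. Naive-like CD8 cells made up 41.4% ± 2.81 against 45.9% ± 0.324, both-marker CD8 cells 13.5% ± 5.29 against 11.4% ± 1.07, and antigen-experienced-like CD8 cells 7.46% ± 4.76 against 6.21% ± 2.53. The log2 ratio of the last of these, 0.23, was -0.62 without Cured replicate 2 and -0.11 without Relapsed replicate 1, and that of both-marker CD8 cells, 0.25, was -0.22 without Cured replicate 1. The edgeR test called 0 of 6 states. Naive-like CD4 cells alone reached an unadjusted p under 0.05, with an adjusted p of 0.176, and the other states were at 0.347 or above. These shares rest on 80 naive-like CD4 cells in the Cured and 36 in the Relapsed libraries. The gate needs a detected UMI, so the depth gap of T cells runs alongside the CD4 and CD8 shares too. T cells with UMIs of neither side numbered 96 of 440 and 89 of 388 in the Cured libraries. They numbered 70 of 271 and 71 of 300 in the Relapsed libraries, a larger share in both. CD4 T cells numbered 52 and 58 against 26 and 23.

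CD8 T cells, the cytotoxic class, were compared for gene expression over 288, 238, 174 and 201 cells in Cured replicates 1 and 2 and Relapsed replicates 1 and 2. Tuba1a, an alpha-tubulin, was higher in Cured at 150 ± 30.8 CPM against 79.3 ± 25.5 (log2 fold change 0.90, SE 0.21, adjusted p = 0.0172), Actg1, a cytoplasmic actin, at 1217 ± 295 against 735 ± 291 (0.72, SE 0.17, adjusted p = 0.0183), and Coro1b, an actin-binding coronin, at 71.1 ± 4.63 against 32.2 ± 8.75 (1.12, SE 0.29, adjusted p = 0.0342). Birc5, which encodes survivin and acts in cell division, was at 22.8 ± 4.60 against 0.928 ± 1.31 CPM (4.56, SE 0.85, adjusted p = 0.000491). Pclaf, a factor of DNA replication, was at 37.3 ± 33.0 CPM against 0 (adjusted p = 0.00346). It falls outside the rule for named genes and was chosen after its values were seen. A floor of 3 UMIs in Relapsed gave a ratio of 15.2 over the group. That ratio takes UMIs as independent, although up to 27 came from 1 cell, so it is no lower bound on the fold.

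Both of those last genes rested on very few cells. Birc5 had 28 and 19 UMIs in the Cured libraries, from 2 cells in each, with 24 and 14 of the UMIs in 1 cell, and 1 UMI in the Relapsed libraries. Pclaf had 15 UMIs from 2 cells and 59 UMIs from 3 cells. Top2a, a topoisomerase of dividing cells that fell below the count filter and was chosen after its values were seen, had 11 UMIs from 6 cells and 17 UMIs from 7 cells in the Cured libraries and 0 in the Relapsed libraries. Cells with at least 3 of 21 cell cycle genes made up 2.08% (exact 95% interval 0.768 to 4.48) and 2.52% (0.931 to 5.41) of CD8 T cells in the Cured libraries, against 2.30% (0.630 to 5.78) and 1.49% (0.309 to 4.30) in the Relapsed libraries. That definition was chosen after the gene calls had been seen. The median depths behind these shares were 3816, 3807, 3250 and 3366 UMIs, in the order given.

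Hnrnpa0, an RNA-binding protein, was lower in Cured CD8 T cells at 35.4 ± 8.03 against 88.4 ± 45.7 CPM (log2 fold change -1.29, SE 0.27, adjusted p = 0.00346). Arl4c, a small GTPase, was at 91.7 ± 0.407 against 174 ± 39.8 (-0.91, SE 0.20, adjusted p = 0.00758), and Cct6a, a chaperonin subunit, at 367 ± 29.4 against 626 ± 13.8 (-0.77, SE 0.17, adjusted p = 0.00758). Bcl11b, a transcription factor of T cell identity, was at 74.0 ± 4.42 against 132 ± 36.5 (-0.82, SE 0.22, adjusted p = 0.0457), and Ddx3x, an RNA helicase, at 30.2 ± 2.00 against 71.5 ± 30.2 (-1.21, SE 0.29, adjusted p = 0.0183). Als2cl, Gramd4, Emsy, Slc12a7, Bcl9l, Zzef1 and Cep350 were lower with log2 fold changes of -1.35, -1.34, -1.44, -1.23, -1.20, -1.50 and -1.62. Scaf11, a splicing-related factor outside the rule for this class and chosen after its values were seen, was at 970 ± 42.4 against 1651 ± 104 (-0.77, SE 0.17, adjusted p = 0.00770).

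In all, edgeR called 23 of 5655 genes in CD8 T cells, 6 higher and 17 lower in Cured, and 479 genes had an unadjusted p under 0.05. The median prior degrees of freedom, the weight of the spread shared over genes, were infinite in this class. For most genes the SE and p therefore do not reflect the gene's own spread between libraries, which was wide for Hnrnpa0, Ddx3x and Actg1. DESeq2 called 1. The groups' libraries did not overlap for 2110 genes (37.3%, where chance gives 33.3%). The count was 13 without Cured replicate 1, 0 without Cured replicate 2, 7 without Relapsed replicate 1 and 78 without Relapsed replicate 2, with the sign kept by each of the 23 genes that could still be tested. Of these 23 genes 3, 0, 5 and 16 were still called, in that order. Without Relapsed replicate 1 Actg1 was at 0.37, Tuba1a at 0.62, Coro1b at 0.88, Hnrnpa0 at -0.68, Arl4c at -0.68, Bcl11b at -0.52, Ddx3x at -0.73, Als2cl at -0.86, Emsy at -0.94, Gramd4 at -0.98, Bcl9l at -0.92 and Slc12a7 at -0.76, none past the test. Cep350 was at -0.95 without Cured replicate 1 and at -2.74 without Cured replicate 2, Actg1 at 0.46 without Cured replicate 2 and Birc5 at 3.53 without Relapsed replicate 2, and none of these passed. The count was 8 with mixed cells kept and 0 at equal depth of 1000 UMIs per cell, which leaves fewer UMIs. At equal depth 10 of the called genes named by the rule could be tested, each with its sign kept and 6 with a log2 fold change at least as large, such as Coro1b at 1.34, while Bcl9l was at -0.48.

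**Figure D2:**
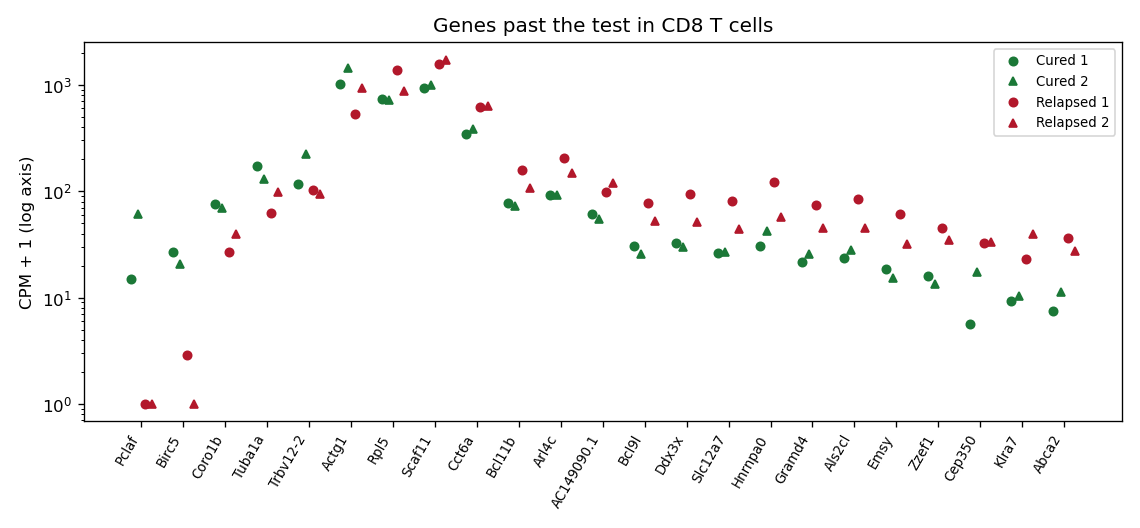
Expression in CD8 T cells (CPM plus 1, log axis) of genes that passed the test, for the 4 libraries, with Cured in green, Relapsed in red, circles for replicate 1 and triangles for replicate 2. Tuba1a lies at 172 and 128 CPM in the Cured libraries and at 61.3 and 97.4 in the Relapsed libraries.

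On GRCm38 (strand in parentheses), Tuba1a lies on chromosome 15 from 98949837 to 98953703 (-), where its exons overlap the predicted gene Gm49450, and it has near-identical tubulin copies, so its counts are uncertain. Actg1 lies on chromosome 11 from 120345690 to 120348542 (-), Birc5 on chromosome 11 from 117849251 to 117855743 (+) and Coro1b on chromosome 19 from 4148619 to 4154035 (+), where its exons overlap those of Ptprcap and its counts are uncertain. Hnrnpa0 lies on chromosome 13 from 58125879 to 58128556 (-), Arl4c on chromosome 1 from 88673125 to 88702221 (-) and Bcl11b on chromosome 12 from 107910403 to 108003602 (-). Cct6a lies on chromosome 5 from 129786998 to 129846371 (+), where the small RNA gene Snora15 overlaps it, and Scaf11 on chromosome 15 from 96411699 to 96460843 (-).

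The genes of T cell function chosen in advance and named here did not pass the test in CD8 T cells. The granzymes Gzmk and Gzmb, proteases of cytotoxic granules, were at 94.5 ± 64.0 against 30.7 ± 17.1 CPM (log2 fold change 1.55, SE 0.48, adjusted p = 0.289) and at 45.8 ± 39.8 against 18.9 ± 0.436 (1.24, SE 0.44, adjusted p = 0.293). For Gzmb the value was -0.10 without Cured replicate 2 and 1.96, past the threshold, without Cured replicate 1. For Gzmk it was 0.64 without Cured replicate 2 and 2.14, past the threshold, without Cured replicate 1. The interferon-induced GTPase Gbp2 was at 50.7 ± 0.549 against 34.8 ± 7.17 CPM (0.52, SE 0.31, adjusted p = 0.660). The interferon-induced Isg15 had a log2 fold change of 0.49 (adjusted p = 0.598), which was -0.08 without Relapsed replicate 2 and 1.27, past the threshold, without Relapsed replicate 1. Stat4, Irf1, Cxcr3, Nkg7, Ccl5, Tox, Socs3 and Cd69 lay between 0.05 and 0.37, and Gata3, Cd44 and Socs1 at -0.41, -0.21 and -0.17. The sign changed when 1 library was left out for Irf1 (-0.02 without Cured replicate 1), Socs3 (-0.60 without Cured replicate 1, -0.07 without Relapsed replicate 1), Ccl5 (-0.38, also -0.27 without Relapsed replicate 1), Nkg7 (-0.10), Tox (-0.08), Cxcr3 (-0.00) and Socs1 (0.08), these without Cured replicate 2, and Cd69 (-0.14 without Relapsed replicate 2). Ifng, Tbx21, Il12rb1, Il12rb2, Pdcd1, Foxp3 and Il2ra had too few UMIs to be tested.

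Among gene lists in CD8 T cells, 5 were higher in Cured. Of the 14 tested cell cycle genes 11 had a positive log2 fold change (median 0.28, adjusted p = 4.93e-05 by camera). Birc5 passed over all genes, and 4 passed when adjusted over the list alone. Stmn1, a microtubule regulator, was at 64.5 ± 30.8 against 30.8 ± 24.7 CPM (1.13, and 0.54 without Cured replicate 2, 0.41 without Relapsed replicate 2, and past the test at 1.56 without Cured replicate 1 and 2.25 without Relapsed replicate 1), and Tuba1b at 245 ± 0.126 against 160 ± 47.4. Of the 12 glycolysis genes 12 were positive (median 0.39, adjusted p = 0.000102), with Pgk1 at 139 ± 14.0 against 101 ± 27.8 CPM and Ldha at 356 ± 7.95 against 278 ± 93.4 (0.35, and 0.04 without Relapsed replicate 1). Of the 27 type I interferon response genes 21 were positive (median 0.27, adjusted p = 0.000679), with Irf7 at 55.2 ± 1.84 against 33.3 ± 5.08 CPM and Ifit1 at 47.3 ± 29.1 against 26.7 ± 14.8. Of the 15 cytotoxic effector genes 13 were positive (median 0.20, adjusted p = 0.00386), with Prf1, which encodes perforin, at 31.4 ± 3.60 against 18.7 ± 2.79 CPM. Of the 13 heat shock and thaw stress genes 11 were positive (median 0.20, adjusted p = 0.0314), with Hspa8 at 1224 ± 171 against 850 ± 109 CPM. Adjusted over the list alone, 1 heat shock gene and 0 genes of the glycolysis, interferon and cytotoxic lists passed. With an estimated correlation the 5 lists had an adjusted p = 0.679, 0.799, 0.679, 0.679 and 0.826, in the order given.

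Another 2 lists were lower in Cured CD8 T cells. Of the 13 mitochondrially encoded transcripts 12 had a negative log2 fold change (median -0.28, adjusted p = 0.000190), with mt-Nd4 at 726 ± 10.0 against 1029 ± 335 CPM (-0.50, and -0.13 without Relapsed replicate 1), and 1 passed when adjusted over the list alone. Of 37 cytosolic ribosomal protein genes 33 were negative (median -0.12, adjusted p = 0.0286) and 0 passed when adjusted over the list alone. With an estimated correlation these lists had an adjusted p = 0.799 and 0.826. Without Relapsed replicate 2 the log2 fold changes were 0.96 for Tuba1b, 0.76 for Ldha and -0.80 for mt-Nd4. Camera thus called 7 of 22 lists, 0 with an estimated correlation and 0 by fry. It called 12 without Cured replicate 1, 8 without Cured replicate 2, 4 without Relapsed replicate 1 and 6 without Relapsed replicate 2, and 3 at equal depth per cell.

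The other 15 lists tested in CD8 T cells did not pass. For the interferon gamma response 17 of 24 genes were positive (median 0.18, adjusted p = 0.0521), with Ifi47 at 276 ± 33.6 against 189 ± 35.8 CPM. The antigen-experienced list had a median of 0.19 (adjusted p = 0.152, 2 genes past over the list alone), with Vim at 392 ± 78.1 against 266 ± 89.6 CPM. The checkpoint and exhaustion list had a median of 0.26 (adjusted p = 0.312, 2 genes past over the list alone), with the inhibitory receptor Tigit at 25.3 ± 12.1 against 8.69 ± 4.41 CPM. The naive and central memory list was at -0.00 (adjusted p = 0.440, 1 gene lower over the list alone), with the chromatin organiser Satb1 at 148 ± 23.3 against 237 ± 72.0 CPM. Medians were 0.07 for MHC class I, -0.07 for MHC class II, 0.19 for the type 1 helper programme, -0.24 for the regulatory programme, 0.08 for immediate early genes, -0.07 for cytokine receptor signalling, 0.20 for NF-kB signalling, -0.03 for oxidative phosphorylation and 0.20 for the p53 response. The median and the mean differed in sign for T cell receptor signalling (0.03 and -0.00, higher by the test) and for T cell transcripts (0.02 and -0.06, lower by the test). Adjusted over the list alone, 1 immediate early gene was higher and 2 were lower, 1 T cell transcript (Bcl11b) was lower, and 0 genes of the others named here passed. Without Relapsed replicate 2 the log2 fold change went from 0.55 to 0.96 for Vim, from 0.54 to 0.77 for Ifi47 and from -0.66 to -0.95 for Satb1.

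**Figure D3:**
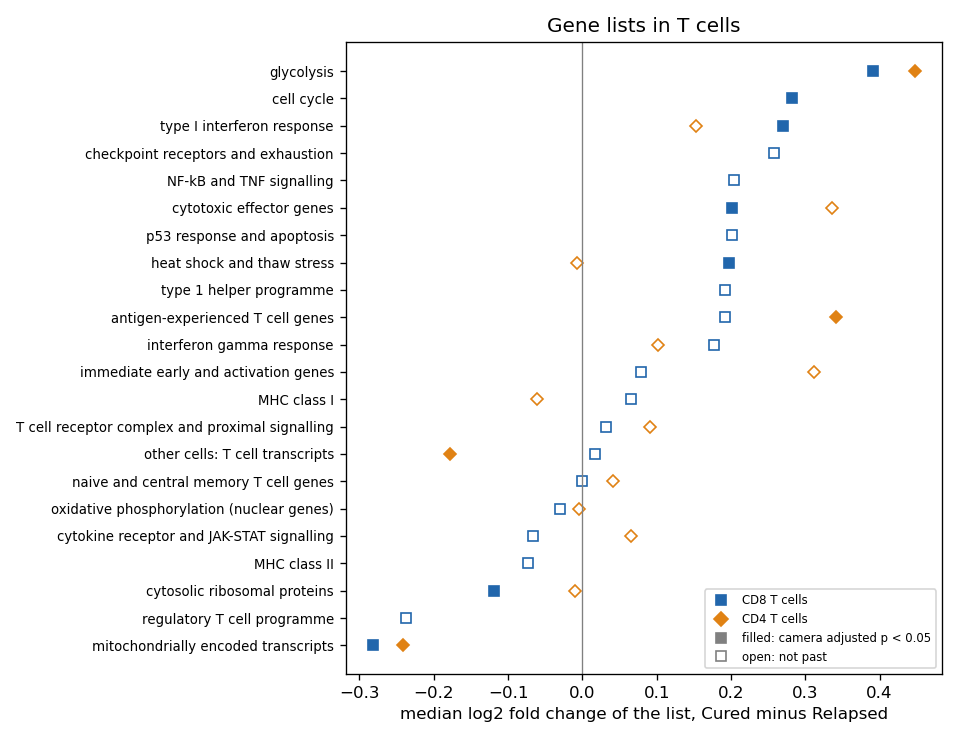
Median log2 fold change (Cured over Relapsed) of the tested members of each gene list in CD4 and CD8 T cells, with filled symbols for lists with a camera adjusted p under 0.05. In CD8 T cells glycolysis lies at 0.39 and mitochondrially encoded transcripts at -0.28.

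CD4 T cells, the helper class, numbered 52, 58, 26 and 23 cells, and few genes could be measured. Gzma, a granzyme, was at 172 ± 34.8 CPM in Cured and 19.9 ± 1.67 in Relapsed libraries (log2 fold change 3.03, SE 0.71, adjusted p = 0.239), which rests on 24 and 19 UMIs against 1 UMI in each Relapsed library. Satb1 was at 255 ± 24.2 against 602 ± 47.5 (-1.24, SE 0.27, adjusted p = 0.239), Ppp1r18 at 460 ± 45.8 against 161 ± 69.5 (1.53, SE 0.36, adjusted p = 0.239) and Hspa8, a heat shock protein, at 1469 ± 395 against 746 ± 76.5 (0.98, SE 0.26, adjusted p = 0.453). Jun, an immediate early transcription factor, was at 460 ± 68.4 against 230 ± 61.3 and Cct6a at 551 ± 188 against 1067 ± 289 CPM. Of the genes chosen in advance, Cd69, Nkg7 and Ccl5 were at 0.45 (-0.34 without Relapsed replicate 1), 0.74 and 0.34, none past the test (adjusted p = 0.995). The edgeR test called 0 of 1155 genes, with 48 at an unadjusted p under 0.05, and DESeq2 called 0. The count was 2 without Relapsed replicate 1, 7 without Relapsed replicate 2 (among them Ppp1r18 at 2.08, Hspa8 and Cct6a), 5 with no count filter and 2 with mixed cells kept.

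Of 15 lists tested in CD4 T cells camera called 4. Glycolysis genes (6 of 6 positive, median 0.45, adjusted p = 0.0327) and antigen-experienced genes (13 of 15 positive, median 0.34, adjusted p = 0.0327) were higher in Cured, with Pkm at 335 ± 21.1 against 193 ± 114 CPM and Klf6 at 215 ± 14.4 against 109 ± 4.89. Mitochondrially encoded transcripts (11 of 12 negative, median -0.24, adjusted p = 0.00999) and T cell transcripts (7 of 10 negative, median -0.18, adjusted p = 0.0327) were lower, with Trbc2, a T cell receptor constant gene, at 347 ± 26.3 against 583 ± 21.1 CPM. Each of these 4 lists had an adjusted p = 0.840 with an estimated correlation and 0 genes past over all genes or adjusted over the list alone, and fry called 0. Leaving receptor, ribosomal and mitochondrial genes out gave 0 calls, 2 at equal depth per cell and 8 with no count filter. Interferon gamma (median 0.10, adjusted p = 0.406), type I interferon (0.15, 0.406), cytotoxic (0.34, 0.310, 1 gene past over the list alone), immediate early (0.31, 0.125), T cell receptor (0.09, 0.524), MHC class I (-0.06, 0.765) and ribosomal lists (-0.01, 0.897) did not pass. The median and the test differed in sign for cytokine receptor signalling (0.06, lower by the test), oxidative phosphorylation (-0.01, higher) and heat shock genes (-0.01, higher, 1 gene past over the list alone), and the median and the mean for the naive list (0.04 and -0.01, 1 gene lower over the list alone).

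Whether CD4 and CD8 T cells differed in their change between Cured and Relapsed was tested directly. The smallest p outside the receptor segments were those of Ppp1r18, with a CD8 minus CD4 difference of -1.41 (SE 0.39), and Gzma, at -2.93 (SE 0.83), both with an adjusted p of 0.992 and both chosen after their values were seen. The edgeR interaction test called 0 of 4307 genes, with 183 at an unadjusted p under 0.05, and DESeq2 called 0. The count was 3 without Cured replicate 1, 3 without Relapsed replicate 1, 57 without Relapsed replicate 2 and 10 with mixed cells kept.

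Monocytes numbered 35, 103, 79 and 120 cells. Vim, the intermediate filament vimentin, was higher in Cured at 2588 ± 185 against 1266 ± 101 CPM (log2 fold change 1.02, SE 0.14, adjusted p = 4.59e-05), and the interferon-induced Ifi27l2a at 3485 ± 484 against 1820 ± 110.0 (0.93, SE 0.13, adjusted p = 7.33e-05). H2-Ab1, an MHC class II chain that presents antigen to CD4 T cells, was higher at 657 ± 267 against 288 ± 100 (1.25, SE 0.25, adjusted p = 0.0424), and Gbp2 at 80.0 and 211 CPM in the Cured against 48.2 and 57.8 in the Relapsed libraries (1.68, SE 0.36, adjusted p = 0.0424). Scaf11 was lower at 386 ± 35.2 against 715 ± 65.1 (-0.91, SE 0.20, adjusted p = 0.0424). Classical monocytes, 1 of the 2 clusters, numbered 14, 59, 41 and 45 cells before mixed cells were removed, and non-classical monocytes 28, 66, 80 and 98. Within the non-classical cluster Vim had a log2 fold change of 0.26 (SE 0.29) and Ifi27l2a of -0.08 (SE 0.24), both with an adjusted p of 1.00.

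Of 20 lists in monocytes camera called 3, each higher in Cured. MHC class II genes (6 of 6 positive, median 1.16, adjusted p = 5.45e-09, 1 past over all genes and 2 adjusted over the list alone) included H2-DMb1 at 178 ± 9.67 against 76.9 ± 20.2 CPM (1.19, and past the test at 1.53 without Relapsed replicate 2). Interferon gamma genes (14 of 17, median 0.30, adjusted p = 0.000128, 1 and 2) included Ifi47 at 188 ± 7.63 against 98.7 ± 23.8, and type I interferon genes (19 of 25, median 0.34, adjusted p = 0.000272, 1 and 1) included Irf7 at 270 ± 6.67 against 160 ± 11.7. Within non-classical monocytes 2 of 5 type I interferon genes were positive (median -0.08, adjusted p = 0.559 by camera), and Irf7 was at -0.46. Of the interferon gamma genes 10 of 11 were positive there (median 0.16, adjusted p = 0.0823 by camera). In all monocytes each of the 3 called lists had an adjusted p = 0.690 by camera with an estimated correlation, and none of the 3 passed by fry. Of 3695 genes edgeR called 5, 4 higher and 1 lower, and DESeq2 called 2. Without Cured replicate 2 the log2 fold change was 0.64 for H2-Ab1 and 0.54 for Gbp2, and neither passed, nor did Scaf11 without either Cured library. H2-Ab1 did not pass with mixed cells kept (0.37) or at a clustering resolution of 0.5 (0.20). The count was 9 without Relapsed replicate 1, 38 without Relapsed replicate 2 and 0 at equal depth per cell, where Vim was at 0.98, Ifi27l2a at 0.83, H2-Ab1 at 1.46 and Scaf11 at -0.51.

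**Figure D4:**
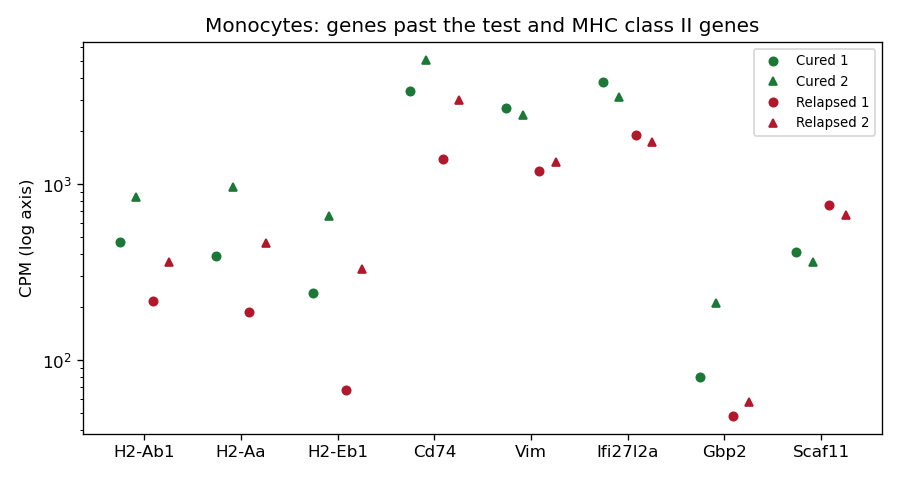
Expression in monocytes (CPM, log axis) of the 5 genes past the test and of further MHC class II genes, for the 4 libraries, with Cured in green, Relapsed in red, circles for replicate 1 and triangles for replicate 2. Vim and Ifi27l2a lie higher in both Cured libraries, and H2-Ab1 lies at 468 CPM in Cured replicate 1 and 359 CPM in Relapsed replicate 2.

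On GRCm38, Vim lies on chromosome 2 from 13573927 to 13582826 (+), Ifi27l2a on chromosome 12 from 103442167 to 103443680 (-), H2-Ab1 on chromosome 17 from 34257689 to 34269419 (+) and Gbp2 on chromosome 3 from 142620602 to 142638008 (+).

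B cells, the most abundant class, were compared over 2652, 2942, 2033 and 3156 cells. Outside the gene groups set apart, Scaf11 had the smallest p among genes of at least 20 CPM, at 917 ± 26.9 CPM in Cured and 1488 ± 22.6 in Relapsed libraries (log2 fold change -0.70, SE 0.11, adjusted p = 0.246). Type I interferon genes were higher in Cured (26 of 36 positive, median 0.28, adjusted p = 0.00101 by camera, 0.765 with an estimated correlation, fry adjusted p = 0.0423), with Usp18 at 6.62 ± 1.93 against 2.91 ± 0.254 CPM. Interferon gamma genes (22 of 31, median 0.15, adjusted p = 0.0230), glycolysis genes (12 of 15, median 0.27, 0.0324) and heat shock genes (10 of 13, median 0.21, 0.0172) were also higher, and mitochondrially encoded transcripts lower (12 of 13 negative, median -0.22, 0.00311). With an estimated correlation these had an adjusted p = 0.799, 0.765, 0.765 and 0.765. Without Relapsed replicate 1 the glycolysis genes Gpi1, Pkm and Ldha went from 0.49, 0.40 and 0.41 to 0.21, 0.19 and 0.15. Scaf11 passed without Relapsed replicate 1 (-0.68) and without Relapsed replicate 2 (-0.71). Adjusted over the list alone, 1 heat shock gene and 0 genes of the other 4 lists passed, and none passed over all genes. The precursor B or leukaemic cell list had a median of 0.08 (adjusted p = 0.762) and the erythroid list of -0.79 (adjusted p = 0.210, 3 genes lower over the list alone). Monocyte transcripts were positive for 7 of 8 genes (median 0.19, adjusted p = 0.187 by camera, 0.0467 by fry). For B cell transcripts (median -0.00, adjusted p = 0.227) 4 genes were lower over the list alone, with the smallest p for Ighd, Ighm and Pax5.

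In B cells edgeR called 0 of 10121 genes, with 971 at an unadjusted p under 0.05, and DESeq2 called 9. The groups' libraries did not overlap for 45.9% of genes, where chance gives 33.3%. The count was 12 without Cured replicate 1, 4 without Cured replicate 2, 12 without Relapsed replicate 1 and 2086 without Relapsed replicate 2, and 203 with no count filter. The B cell clusters were filled unevenly. A cluster led by Ighd, with Pax5 further down its leading genes, held 293 and 298 Cured against 711 and 486 Relapsed cells. Another cluster with Ighd among its leading genes held 602 and 825 against 766 and 708. These counts are from before mixed cells were removed.

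NK cells numbered 174, 194, 193 and 237. MHC class II genes were higher in Cured (5 of 5 positive, median 0.97, adjusted p = 0.000271 by camera, 0.623 with an estimated correlation, 3 past adjusted over the list alone), with Cd74 at 277 ± 139 against 139 ± 17.1 CPM. Without Cured replicate 1 the log2 fold change went from 0.97 to 0.36 for Cd74 and from 1.09 to 0.65 for H2-Aa. Cytotoxic effector genes (16 of 21, median 0.16, adjusted p = 0.00361), with Gzmb at 1202 ± 126 against 873 ± 191 CPM (0.46, 0.24 without Relapsed replicate 1 and past the test at 0.74 without Relapsed replicate 2), and heat shock genes (9 of 13, median 0.13, adjusted p = 0.00361) were higher. Ribosomal (33 of 37 negative, median -0.16, adjusted p = 5.36e-07), mitochondrially encoded (11 of 13, median -0.21, adjusted p = 0.000502) and oxidative phosphorylation genes (25 of 29, median -0.07, adjusted p = 0.0380) were lower. Each had an adjusted p = 0.623 with an estimated correlation. Adjusted over the list alone, 1 heat shock gene and 0 genes of the cytotoxic, ribosomal, mitochondrially encoded and oxidative phosphorylation lists passed. The T cell receptor chain gene Cd3d, a T cell marker, was at 89.1 ± 12.8 against 29.3 ± 4.60 CPM in NK cells (adjusted p = 0.326, and past the test without Relapsed replicate 2). T cell markers did not make an NK cell mixed, so cells that carried both were kept here. In NK cells edgeR called 0 of 4805 genes, with 309 at an unadjusted p under 0.05, and DESeq2 called 0. The count was 5 without Cured replicate 2, 2 without Relapsed replicate 1 and 205 without Relapsed replicate 2.

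Neutrophils numbered 243, 208, 385 and 177 cells. MHC class I genes were higher in Cured (9 of 11 positive, median 0.23, adjusted p = 0.0183 by camera) and mitochondrially encoded transcripts lower (11 of 11 negative, median -0.45, adjusted p = 0.000581), and both had an adjusted p = 0.703 with an estimated correlation. H2-Q7 was at 259 ± 11.1 against 175 ± 24.9 CPM. Ifi27l2a was at 2089 ± 804 against 1194 ± 151 (log2 fold change 0.81, SE 0.22) and Ly6e at 1033 ± 31.9 against 687 ± 51.6 (0.58, SE 0.19), both with an adjusted p of 0.999. Ifi27l2a was at 0.35 without Cured replicate 1 and passed at 0.94 without Relapsed replicate 2. Neutrophil transcripts were negative for 17 of 18 genes (median -0.17, adjusted p = 0.177) and monocyte transcripts had a median of 0.17 (adjusted p = 0.424), neither past camera. The edgeR test called 0 of 2693 genes, with 122 at an unadjusted p under 0.05, and DESeq2 called 0. The count was 1 without Cured replicate 1, 6 without Relapsed replicate 1 and 25 without Relapsed replicate 2. The type 2 helper, follicular helper and platelet lists had fewer than 5 tested members in each class.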

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

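The tests of the B-lineage cluster were chosen after the results were seen. The Y-linked genes are Ddx3y, Eif2s3y, Kdm5d and Uty. The added sequence GFP_1 and the Y-linked genes, which no comparison used, gave UMIs above the limit of 3 counts. GFP_1 had 4 UMIs in Cured replicate 2, 6 in Relapsed replicate 1 and 13 in Relapsed replicate 2, and 0 in Cured replicate 1. Y-linked genes had 37, 31 and 65 UMIs in those libraries and 3 in Cured replicate 1. BCR_ABL_1 had 0 UMIs in each library, which does not show that leukaemic cells were absent, since whether this chemistry captures that sequence was not given in the sources used here.

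Most of these UMIs lay in a B-lineage cluster of 189 cells that carried Cdkn2a, a cell cycle inhibitor locus (chromosome 4 from 89274471 to 89294653, - strand, GRCm38). It held 109 of the 136 Y-linked UMIs, 15 of the 23 GFP_1 UMIs and 236 of the 282 Cdkn2a UMIs. Its share of kept cells was 0.291% (exact 95% interval 0.145 to 0.521) in Cured replicate 1, 1.19% (0.878 to 1.56) in Cured replicate 2, 1.48% (1.09 to 1.95) in Relapsed replicate 1 and 1.90% (1.51 to 2.35) in Relapsed replicate 2, with means of 0.738% in Cured and 1.69% in Relapsed. The log2 ratio was -1.18 (SE 0.75), which did not pass the edgeR test (adjusted p = 0.460) with n = 2 per group. Its median depth was 4792 UMIs, against 2143 in B cells.

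At an equal depth of 1000 UMIs, 11.1% of its cells had a Y-linked UMI (7.01 to 16.5), against 0.0377% of B cells, and 0 of 1325 T cells, which allows up to 0.226%. The lower bound of 7.01% lies above 2 times the upper bound in B cells (0.193%), more than pairs of host B cells would bring, although these UMIs prompted the test (sex-linked genes took no part in the clustering). Xist was found in 16.9% of its cells (11.9 to 23.1), against 38.4% of B cells, and this test alone left such doublets open for the rest of the cluster. Of the 67 cells with a Y-linked UMI 1.49% had Xist, against 48.4% of the 122 without. A candidate explanation is that part of the cluster came from a male donor, such as the inoculated cells, which is a hypothesis, since the sex of the mice was not given in the sources used here and no test tied these cells to leukaemia.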

How the results depend on the processing

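Alternatives on all T cells, on naive-like CD8 T cells, without NK-receptor T cells and with low-UMI cells as B cells were chosen after the data were seen. Class shares and T cell state shares gave 0 calls under each of 14 and 13 alternatives, the replicate block included. The gene counts moved most when 1 library was left out, when a group's lone library was assumed to vary like the others. The ranges were 0 to 7 genes in CD4 T cells, 0 to 78 in CD8 T cells, 4 to 2086 in B cells, 0 to 205 in NK cells, 6 to 38 in monocytes, 0 to 25 in neutrophils and 0 to 57 in the interaction. For lists they were 3 to 6 in CD4 and 4 to 12 in CD8 T cells. The upper end of each gene range came without Relapsed replicate 2, where Relapsed replicate 1 stood alone for its group. The called CD8 genes had a median of 0.77 of their main log2 fold change without Relapsed replicate 1 and 1.24 without Relapsed replicate 2. Relapsed replicate 1 had the lowest median UMIs per barcode (1738) and the highest median mitochondrial share (2.44%). With no count filter the counts were 5 (CD4), 203 (B), 7 (NK), 3 (neutrophils) and 1 (interaction), and 8 CD4 lists. The DESeq2 Wald test gave 1 (CD8), 9 (B) and 2 (monocytes). A non-robust fit gave 1 in NK cells and 3 in monocytes. At equal depth of 1000 UMIs the counts were 1 (CD4), 0 (CD8), 0 (monocytes), 2 CD4 lists and 3 CD8 lists. This setting also leaves out shallower cells, and the log2 fold changes of called genes mostly stayed of similar size (Vim in monocytes 0.98, Coro1b in CD8 T cells 1.34). With doublets kept they were 2 (CD4), 8 (CD8), 3 (NK), 2 (neutrophils) and 10 (interaction). Marker gates gave 1 in CD4 T cells and 13 in monocytes. A mitochondrial limit of 5% gave 2 in monocytes and resolution 0.5 gave 2. Leaving receptor, sex-linked, mitochondrial and ribosomal genes out gave 1 in B cells and 0 CD4 lists. Naive-like CD8 T cells alone gave 0 genes, and all T cells 0 genes and 4 CD8 lists. Camera with an estimated correlation and fry gave 0 lists in both classes. Where no sentence gives a reason, the cause was not tested. Of 3738 values of 225 single results, 3488 kept their side of the threshold, 155 fell short of it, 95 moved past it and 0 reversed a call. Only results called in the main fit could fall short, so all 155 came from those. Results that stayed uncalled counted as kept whatever their sign. A called gene kept its call in between 7 of 19 alternatives (Coro1b in CD8 T cells) and 15 of 16 (Vim in monocytes).

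The labels did not say whether samples with the same replicate number shared a thaw or capture day, so only the number is known to be shared. With the replicate block the counts were 152 in B cells, 4 in NK cells and 2 in neutrophils, against 29 in CD8 T cells, 5 in monocytes, 0 in CD4 T cells, 9 CD8 lists and 4 CD4 lists. Deviations of samples with the same number correlated at -0.02 (CD4), 0.02 (CD8), 0.04 (B), -0.05 (NK), 0.06 (monocytes) and 0.06 (neutrophils), and over genes of at least 50 CPM at 0.14 in CD8 T cells. The interaction has no such fit, because its library block contains the number. Of the 6 classes of the design CD4 T cells had the fewest UMIs, 57259 in the smallest library.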

Other observations

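The tests of a shared shift, of B cell RNA and of the monocyte mix were chosen after the results were seen, and the predictions for transcript length and the CD8 state mix before those tests were run, but after the CD8 calls and the leading genes in naive-like T cells had been seen. Some groups moved alike across cell classes. Mitochondrially encoded transcripts were lower in Cured in CD4 T, CD8 T, B and NK cells and neutrophils by camera, with medians of -0.24, -0.28, -0.22, -0.21 and -0.45. With an estimated correlation their adjusted p = 0.840, 0.799, 0.765, 0.623 and 0.703. Relapsed replicate 1 carried much of it, since without that library mt-Nd4 in CD8 T cells went from -0.50 to -0.13, mt-Co3 in NK cells from -0.49 to -0.18 and mt-Nd1 in neutrophils from -1.34 to -0.12. Hspa8, which folds proteins under stress, was positive in each of 6 classes, from 0.50 in neutrophils to 0.98 in CD4 T cells, and passed in none (smallest adjusted p = 0.0585, monocytes). Vim was positive in 6 classes and passed in monocytes alone, a difference between classes that was not tested. A B cell cluster led by the interferon-induced Ifit3, Serpina3g and Ly6a held 315, 521, 120 and 419 cells of Cured replicates 1 and 2 and Relapsed replicates 1 and 2, before mixed cells were removed.

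In naive-like T cells, a class added later, edgeR called Scaf11 (932 ± 161 against 1521 ± 130 CPM, log2 fold change -0.71, adjusted p = 0.0306) and Gm42418 (12770 ± 113 against 25000 ± 3937 CPM, -0.97, adjusted p = 6.97e-07), a predicted gene, both lower in Cured. In non-classical monocytes it called H2-Ab1 (824 ± 608 against 235 ± 50.9 CPM, 1.91, SE 0.31, adjusted p = 1.64e-06) and Cd74, the MHC class II chaperone (5081 ± 2530 against 2117 ± 859, 1.28, SE 0.27, adjusted p = 0.0480), both higher in Cured. As in CD8 T cells, the median prior degrees of freedom were infinite in this class. The SE and p of H2-Ab1 therefore do not reflect its own wide spread between the 2 Cured libraries. Gm42418 did not pass in the classes of the design. It was at -0.65 in CD8 T, -1.48 in CD4 T, -0.56 in B and -0.49 in NK cells, -0.29 in monocytes and 0.19 in neutrophils.

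The 17 genes lower in Cured CD8 T cells may belong to a shift shared by the cells of a library. Of the 13 tested in B cells 92.3% were negative there, against 45.0% of all genes. Of all 5485 genes tested in both classes 69.1% had the same sign, so part of that excess is general, and a library-wide difference, technical or in the mice, stays open. Transcript length stays open too, since the 16 genes with a value had a median exonic length of 6.94 kb against 4.20 kb, at percentile 75.7 (bootstrap interval 56.7 to 90.6), only just above the bound of 75. A different mix of naive-like and other CD8 T cells is argued against. In naive-like CD8 T cells the median was 95.8% of that in all CD8 T cells (-1.17 against -1.22, 16 of 16 negative). These cells were part of the CD8 T cells in which the genes were called. The naive-like state pooled T cell sub-clusters of 471 and 430 cells, and a shift between them was not tested.

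The MHC class II genes higher in Cured monocytes could reflect B cell RNA in the droplets. A share of 6.80% B cell RNA would be needed, and B cell transcripts outside MHC class II were higher by 9.97% of what that share would bring, with 14.5% as the largest value between 2 libraries, which argues against it. A different mix of monocytes stays open for these genes. Within the non-classical cluster 5 of 5 tested genes were positive, so the rise was also seen there. The list's median was 126% of that in all monocytes (1.47 over 5 genes against 1.16 over 6), which compares unlike gene sets. The value within the cluster rests on as few as 23 cells in a library, with H2-Ab1 at 824 ± 608 CPM in Cured. Classical monocytes, with 14 cells in Cured replicate 1 before mixed cells were removed, were not tested on their own. The test within the non-classical cluster covered MHC class II alone. Vim (0.26 against 1.02), Ifi27l2a (-0.08 against 0.93) and the type I interferon list (median -0.08 against 0.34) were smaller or turned negative within that cluster. A mix stays open for them too. Summed MHC class II CPM in monocytes was 4490 and 7451 in Cured and 2049 and 4189 in Relapsed libraries. A difference between the mice and a chance spread over 2 libraries per group therefore both stay open. Dendritic cells sorted into or out of the monocytes stay open as well, since no test covered them. At the lower clustering resolution no dendritic cluster was formed, and H2-Ab1 was at 0.20 in monocytes. Its UMIs in the main classes came from 12 and 38 monocytes in the Cured and 17 and 22 in the Relapsed libraries. Cured replicate 2 had as many as 73 of them per cell.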
